A study of Mus musculus with 2 samples.

How the data were processed

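Liver RNA from male 129SvEJ mice, 8 weeks old, was measured on short oligonucleotide expression arrays that carry 45101 probe sets, of which 64 are controls. Wild-type mice and mice lacking PPARα (Ppara-null) both received chow with 0.2% fenofibrate for 7 days. Per the labels, RNA of 3 mice was pooled for each genotype and each pool was hybridised to 1 array. The data therefore hold 2 arrays and 1 sample per group. No array of mice on a diet without fenofibrate was analysed here.

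The deposited table gives 1 signal intensity per probe set and array on a linear scale. Per the labels, the authors used the Affymetrix statistical algorithm, which summarises the probe pairs of a probe set and scales all probe sets of an array to a target of 1000. The values bear out the target, since the mean without the lowest and highest 2% of probe sets was 1000.01 on each array. The labels give the same scaling factor, 22.9, and the same background text for both arrays. Because 1 text serves both arrays, these settings cannot be assigned to an array and were not used. The software version and the detection calls are not given in the sources used here.

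Gene names came from the platform annotation of 2016. Of the 45037 probe sets that are not controls, 34945 had 1 gene symbol, 932 had several and 9160 were unnamed here. Gene identifiers of 34754 of the 34945 were found in the RefSeq gene table of GRCm38.p6, which changed 0 symbols. Probe sets with several symbols or none were kept out of all gene values. No genome build is named for the array values, so no coordinates are given.

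The signals were used as deposited, without further scaling. A floor was set for each array at the median signal of its probe sets that are not controls, which was 287.8 on the wild-type array and 269.4 on the null array. Signals under the floor were raised to it before the log2 ratio of wild type over null was taken. A gene was represented by the probe set with the highest mean log2 signal over both arrays, and counted as measured when at or above the floor on at least 1 array. Genes above the floor on 1 array only have a bound, written as at least N-fold. Of 18193 named genes, 13041 were measured, 10060 of them on both arrays.

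With 1 array per genotype, no test, standard error or p-value can be had, and genes were called by size, at 2-fold or more. The number of arrays limits the precision. As a measure of scatter inside this pair of arrays, the log2 ratios of different probe sets of 1 gene had a pooled SD of 0.42, over 10117 probe sets of 3917 genes measured on both arrays. That SD leaves out differences between mice and between pools. For gene lists, the median log2 ratio of the measured members was placed among the medians of 10000 random lists of equal size, matched on mean signal in 20 bins. The percentile describes these 2 arrays and is no p-value, since genes are not independent replicates. It was given for lists with at least 3 measured members.

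The 25 gene lists, the 12 marker lists, the floor, the 2-fold threshold, the rule for named genes and all alternatives but 2 were fixed before the data were examined. Named genes were Ppara, then the 12 largest ratios in each direction among genes measured on both arrays whose other probe sets had the same sign where these too were above the floor on both arrays, then the 5 largest bounds in each direction. The 3 largest members of each list served as examples, and members at least 2-fold apart could be named. For a probe set of opposite sign, 1 gene was passed over in the higher direction and 2 in the lower.

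The procedure was tested on simulated data made from the mean signals of these arrays, over 18193 genes, with noise of the SD above and 200 changed genes (50 of each kind). At a planted log2 change of 3, 100% of the higher and 100% of the lower genes were called. At a planted change of 1.5, 82% of the higher and 78% of the lower genes were called. Among 11996 unchanged measured genes, 100 were called higher and 95 lower. The noise was the same at all signals, and its SD came from probe sets above the floor on both arrays. Changes were planted only in genes with a mean signal at or above the mean of the floors. The rates of calls may therefore be too favourable for dim genes. Of 100 unchanged random lists, 7 fell outside the middle 95% of their matched lists.

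Alternatives were median centring, quantile normalization, loess removal of the signal-dependent trend, scaling to the hybridization controls, floors at the 25th and 75th percentile, no floor, the median over the probe sets of a gene, omission of probe sets ending in _x_at or _s_at, and thresholds of 1.5-fold and 3-fold. Scaling to the controls was computed first by the difference between the arrays' median log2 signals of the 18 control probe sets. After its results were seen it was replaced by the median of the log2 ratios of these probe sets, since the medians of the arrays can rest on different probe sets. The replacement is thus an alternative chosen after seeing the data, and results of both are given. Floors at the brightest of the 27 Bacillus control probe sets, 316.5 on the wild-type array and 422.4 on the null array, were also added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.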

Results

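Fenofibrate is a lipid-lowering drug that activates PPARα, a nuclear receptor of hepatocytes encoded by Ppara. The study compared liver transcripts of wild-type and Ppara-null mice fed the drug for 7 days, with 1 array of a pool of 3 mice per genotype. The contrast is therefore between genotypes on the same diet, and it joins any difference present without the drug with any difference in response to it. There are no replicates, so no difference below has a replicate check, and all values are single measurements with their size alone. Signals ran from 0.7 to 234616 on the wild-type array and from 0.9 to 269000 on the null array. Log2 signals of the 2 arrays correlated across all 45037 probe sets (Pearson r = 0.84) and more closely across the 18448 probe sets above the floor on both arrays (r = 0.96). Both coefficients are across probe sets, which are not independent replicates.

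The targeted gene itself had a lower signal on the null array at all of its 3 probe sets. Ppara gave 7957 against 3414 (wild type against null) at the brightest, 5833 against 2953 at the next, and 4312 against 1551 at the dimmest. The null signals were 42.9%, 50.6% and 36.0% of wild type and were 12.7, 10.96 and 5.76 times the floor. The labels do not say which part of the gene was disrupted, so it is open whether any of these probe sets lies in it.

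The named genes with the largest differences towards wild type included enzymes and transporters of lipids beside genes of other functions. Cyp4a14, a fatty acid omega-hydroxylase, gave 104679 in wild type and 44.0 in null, a difference of at least 389-fold. Vnn1, the pantetheinase vanin 1, was 172-fold higher (52793 against 307.4), and its other probe set gave 18104 against 9.2. Cyp4a31, a further omega-hydroxylase, was 43.4-fold higher, although genes of this cluster are near-identical and the array may not separate them. Cox6b2, which encodes a subunit of cytochrome c oxidase, was 35.8-fold higher, the fatty acid transporter Cd36 17.8-fold and lipoprotein lipase (Lpl) 10.98-fold. Rtn4 (8.95-fold), Serpina7 (8.91-fold), Retsat (8.89-fold), Aldh3a2 (8.35-fold), Ech1 (7.98-fold), Mfsd2a (7.87-fold) and the phospholipid transfer protein gene Pltp (7.87-fold) completed the 12 largest ratios. The null signals of Vnn1 and of Serpina7 (281.2) lay under that of the brightest Bacillus control probe set on the null array (422.4), so they cannot be told from background and both folds are uncertain. With the floors set at the brightest Bacillus controls, the ratios of Vnn1 and Serpina7 and the bounds of Cyp4a14, Rad51b, Fitm1, Mogat1 and Krt23 were smaller and stayed over 2-fold. Among genes under the floor in null, Rad51b was at least 32.7-fold higher, Fitm1 at least 17.1-fold, Mogat1 at least 9.21-fold and Krt23 at least 8.997-fold. The Rad51b value came from a single probe set, since the other gave 48.7 in wild type and 289.0 in null.

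In the other direction, Nnmt, the nicotinamide N-methyltransferase, was 20.0-fold lower in wild type (532.2 against 10658). Apoa4, an apolipoprotein of triglyceride-rich particles, was 6.84-fold lower (13744 against 94020), and its second probe set gave 3871 against 65549. The organic anion transporters Slc22a7 and Slco1a4 were 5.76-fold and 4.12-fold lower, the metallothionein Mt2 4.84-fold, and the liver pyruvate kinase gene Pklr 4.04-fold. Gtf3c4 (4.07-fold), Pak4 (3.95-fold), Sdf2l1 (3.56-fold), Cln3 (3.55-fold), Olfml1 (3.54-fold) and Aldh1b1 (3.46-fold) followed. A further probe set, above the floor in wild type only, pointed the other way for Cln3 (log2 ratio 0.24) and Gtf3c4 (0.17), and the wild-type signal of Cln3 (306.0) lay under the brightest Bacillus control there (316.5). Rgs16, a regulator of G-protein signalling, was at least 9.80-fold lower, Trpc4ap at least 6.19-fold, Myh10 at least 5.34-fold, Gga1 at least 4.61-fold and Lrtm1 at least 4.07-fold, while another probe set of Lrtm1 had a log2 ratio of 0.35.

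In all, 651 of 13041 measured genes were at least 2-fold higher in wild type and 365 at least 2-fold lower, which are 4.99% and 2.80%. Of these, 363 and 225 were measured on both arrays. At 4-fold or more, 57 genes were higher and 15 lower. Log2 ratios of the 10060 genes measured on both arrays had a median of -0.02 and lay between -0.78 and 0.88 for the middle 90%. Higher genes made up 64.1% of the 2-fold calls as deposited, 50% after median centring (507 and 507 genes) and 90% after scaling to the hybridization controls by the difference of their medians (1350 and 150 genes). Scaling to these controls by the median of their log2 ratios, a way chosen after seeing the data, gave 94.2% (1759 and 109 genes) and is the control scaling named below. These 2 ways moved the median log2 ratio of measured genes from 0.005 to 0.28 and 0.38, so directions below are relative to the deposited scaling. The dimmer signal lay under the brightest Bacillus control for 444 of the 651 higher and 161 of the 365 lower genes. With floors at these controls, chosen after seeing the data, 297 genes were at least 2-fold higher and 303 lower (49.5% higher). These floors were 422.4 on the null array and 316.5 on the wild-type array, which by construction weighs against higher calls. The lower share of higher genes is therefore no result about the genes.

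**Figure D1:**
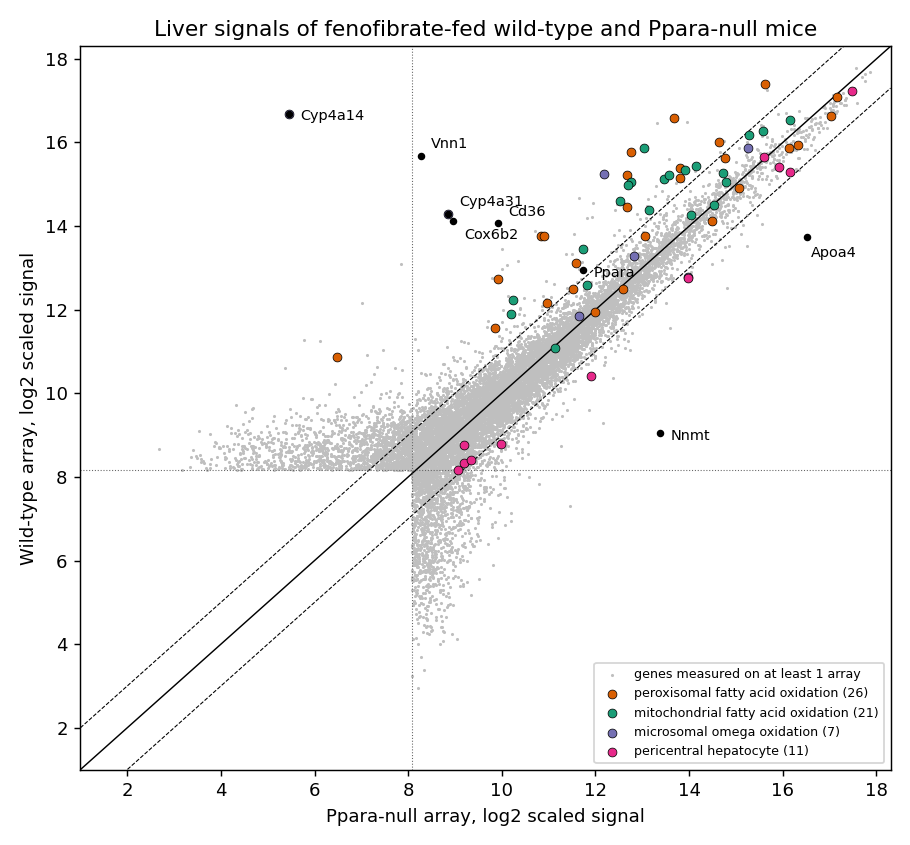
Scaled signals of the measured genes on the Ppara-null array (x axis, log2) and the wild-type array (y axis, log2), 1 point per gene. The solid line marks equality, dashed lines 2-fold differences and dotted lines the floors. Coloured points are members of 4 gene lists. Vnn1 (172-fold, uncertain because its null signal cannot be told from background) and Nnmt (20.0-fold) lie far on either side of the line.

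Genes of peroxisomal and mitochondrial fatty acid oxidation were higher in wild type as lists. Of 26 measured peroxisomal genes, 15 were at least 2-fold higher and 0 lower, with a median of 2.55-fold and log2 ratios with an SD of 1.21 across members. Ech1 (7.98-fold), Acot3 (7.60-fold), the bifunctional enzyme Ehhadh (7.46-fold; 98088 against 13156), Decr2 (7.27-fold) and Acot8 (7.08-fold) led, and the peroxisome proliferation gene Pex11a was 3.46-fold higher. Of the 11 members under 2-fold 8 had negative log2 ratios, lowest for Phyh (-0.38), catalase (Cat, -0.37) and Pxmp2 (-0.36), named here after their values were seen. Of 21 measured mitochondrial genes, 12 were at least 2-fold higher and 0 lower, with a median of 2.44-fold (SD 0.83 on the log2 scale). Eci1 (7.17-fold), the carnitine-acylcarnitine carrier Slc25a20 (4.93-fold), the long-chain dehydrogenase Acadl (4.83-fold) and Cpt2 (3.27-fold) were among them, while Cpt1a, also named after its value was seen, had a log2 ratio of 0.22. In 0 of 10000 matched random lists was the median as high as in either list.

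Of 7 measured genes of microsomal omega oxidation, Cyp4a14, Cyp4a31 and Aldh3a2 were at least 2-fold higher and Cyp4f14 was 2.27-fold lower. The median was 1.52-fold, reached by 9 of 10000 random lists. Only 3 genes of ketone body synthesis were measured. The hormone gene Fgf21 was at least 3.50-fold higher (942.2 against 168.9), Acat1 1.71-fold higher, and Bdh1 had a log2 ratio of -0.04. With floors at the brightest Bacillus controls the bound of Fgf21, and those of Abcc4 and Hao2 given below, were smaller and stayed over 2-fold. The median of the 3 genes was at the 97.6th percentile of the matched lists, at the edge of the middle 95%. It was inside in 4 of 8 alternatives, namely no floor (percentile 97.0), median centring and both control scalings (97.4 each). Centring and control scaling shift all log2 ratios alike, so there the move to 97.4 reflects only a new draw of random lists.

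Genes of fatty acid uptake, binding and activation had a median of 1.74-fold, with 6 of 16 measured members at least 2-fold higher and 0 lower. Cd36, Lpl and the acyl-CoA thioesterase Acot1 (5.21-fold) were the largest, followed by Acsl5 (2.47-fold), Fabp2 (2.20-fold) and Fabp4 (2.13-fold). Lipid droplet and lipolysis genes had a median of 1.76-fold, with 6 of 14 at least 2-fold higher and 0 lower. Among these were Fitm1, the perilipins Plin5 (7.11-fold) and Plin2 (3.19-fold), Fitm2 (3.36-fold) and Mgll (2.67-fold). In 0 of 10000 random lists was the median as high as in either. Lipoprotein genes as a list stood inside the matched lists (19.9th percentile, median log2 ratio -0.16), with Pltp and Apoa4 apart in opposite directions and 14 of 16 members under 2-fold. That median turned positive, at 0.22, after scaling to the hybridization controls.

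Lipid synthesis genes were also higher in wild type as lists, by smaller medians. Of 26 measured genes of fatty acid and triglyceride synthesis, 5 were at least 2-fold higher, among them Mogat1, malic enzyme Me1 (4.06-fold), the stearoyl-CoA desaturase Scd1 (3.04-fold) and Fads2 (2.63-fold), and Pklr was lower. Their median log2 ratio was 0.19 (99.6th percentile), or 0.05 (percentile 90.3) when the probe sets of a gene were summarised by their median. Cholesterol synthesis genes had a median log2 ratio of 0.35 (3 of 10000 random lists as high), with Idi1 (2.18-fold), Hsd17b7 (2.10-fold) and Hmgcs1 (2.03-fold) at least 2-fold higher and 0 of 20 lower. Of these 20 genes, 1 was at least 2-fold higher after median centring and 0 with the median over the probe sets of a gene, where the list median was 0.43. Genes of bile acid synthesis and transport had a median log2 ratio of -0.32 (24 of 10000 random lists as low), which turned to 0.06 after scaling to the hybridization controls. Slco1a4, the rate-limiting enzyme gene Cyp7a1 (2.41-fold; 11590 against 27930) and Cyp7b1 (2.03-fold) were lower, and Abcc4 (at least 3.84-fold) and the phospholipid exporter Abcb4 (2.25-fold) were higher. In glucose, glycogen and glycerol metabolism, the pyruvate dehydrogenase kinase Pdk4 was 3.80-fold higher, and 0 of 15 measured genes were at least 2-fold lower. The list stood at the 35.4th percentile, with a median log2 ratio of -0.10 that became 0.28 under the control scaling. With the median over probe sets it was -0.37 (percentile 0.28).

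Genes of amino acid catabolism and the urea cycle and of acute phase and complement were lower in wild type as lists, mostly by under 2-fold. Of 25 measured genes of amino acid catabolism and the urea cycle, 22 had a negative log2 ratio and 3 were at least 2-fold lower, namely Ass1 (2.80-fold, at a dim probe set of 501.4 and 1406), Prodh (2.56-fold) and Got1 (2.51-fold). The median log2 ratio was -0.43, as low in 0 of 10000 random lists. Of 26 acute phase and complement genes, 23 were negative and Orm3 (2.27-fold) was at least 2-fold lower, with a median of -0.43 (0 of 10000). Saa1 and C6 were 1.94-fold and 1.92-fold lower. Genes of endoplasmic reticulum stress had a median of -0.40 (14 of 10000 as low), with Sdf2l1 at least 2-fold lower and Xbp1 1.78-fold lower. After scaling to the hybridization controls these medians lay at -0.05, -0.05 and -0.02. The 8 measured hepatocyte markers were all lower in wild type, with a median log2 ratio of -0.30 (percentile 5.53) that became 0.08 under the control scaling.

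Xenobiotic cytochrome P450 genes had a median of -0.23 (percentile 2.73), with Cyp2c38 (3.54-fold) and Cyp2c39 (2.34-fold) higher and Cyp2c54 (3.26-fold) lower. Among conjugation and oxidative stress genes, Gstt2 (2.68-fold), the epoxide hydrolase Ephx2 (2.46-fold) and Gstm4 (2.05-fold) were higher, and the list stood at the 13.5th percentile with a median of -0.15. Both medians turned positive under the control scaling, at 0.15 and 0.23. Male-biased liver genes had a median of -0.44 (13 of 10000 as low), with Hsd3b5 (2.04-fold) and Cyp7b1 lower. That median was -0.06 after scaling to the hybridization controls. Female-biased genes had a median of -0.06 (31.5th percentile), or 0.32 under the control scaling, with Acot3 and Hao2 (at least 5.78-fold) higher. With floors at the brightest Bacillus controls 4 members were left, with a median of 0.76 (percentile 99.8), so the position of this list depended on the floor.

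Cell cycle genes had a positive median in wild type over null at low signals. Of 18 measured members 17 were positive, but 9 of these were under the floor in null and counted as measured through wild type alone, which fixes their sign. With no floor, 15 of 26 members were at least 2-fold higher and 3 lower. With the main floor, 6 were at least 2-fold higher and 0 lower, with a median of 1.84-fold (0 of 10000 random lists as high). Cyclin D1 (Ccnd1) was 2.61-fold higher (1997 against 766.3), Rrm2 2.59-fold and Mcm5 2.15-fold, and Mcm4 (at least 2.83-fold), Cdc20 (at least 2.49-fold) and Cdk1 (at least 2.21-fold) were under the floor in null. Another Cdc20 probe set pointed the other way (44.9 against 440.9), and with the median over probe sets 3 of 19 measured members were at least 2-fold higher. The null signals of 5 of the 6 genes lay under the brightest Bacillus control, and with the floors there 2 genes, Ccnd1 and Rrm2, were at least 2-fold higher and the list median was 0.50. The median log2 ratio, 0.88 with the main floor, was 0.22 with the floor at the 75th percentile.

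Pericentral hepatocyte genes, which mark the zone around the central vein, were lower in wild type, with a median log2 ratio of -0.87 (0 of 10000 random lists as low). Of 11 measured members 10 were negative, and Slc1a2 (2.83-fold), Gulo (2.34-fold) and Rhbg (2.30-fold) were at least 2-fold lower, while glutamine synthetase (Glul), named after its value was seen, had a log2 ratio of 0.07. The list median was -0.49 after scaling to the hybridization controls and -0.51 with the median over probe sets. Some members were dim in wild type: Slc1a4 (287.5) lay under the floor, and Axin2 (320.8) and Lgr5 (337.4) just above the brightest Bacillus control (316.5). With floors at these controls the median was -0.86, and 3 members were at least 2-fold lower. Probe sets disagreed for Slc1a2, where another had a log2 ratio of 0.23, and for Lgr5, with -0.94 and 0.92. Periportal genes had a median of -0.21 (16.0th percentile), or 0.17 under the control scaling.

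Among clock genes, Dbp was 2.71-fold lower and Per2 1.93-fold lower, and Arntl was 1.95-fold higher. Their median of -0.32 (62 of 10000 as low) moved to -0.10 (21.8th percentile) with the median over probe sets and to 0.06 under the control scaling. Immediate early genes had a median of -0.30 (percentile 2.39), or 0.07 under the control scaling, with Myc (2.16-fold) higher and Junb (at least 2.25-fold) lower. The list lay inside the middle 95% in all 8 alternatives for which a percentile was computed (2.71 to 3.82). Median centring and both control scalings shift all log2 ratios alike, so their 2.71 differs from 2.39 only by a new draw of random lists. The list thus lay at the edge of the middle 95%. Oxidative phosphorylation genes kept within 2-fold for all 29 measured members, with a median log2 ratio of 0.17 (31 of 10000 as high) and 23 positive. That median was 0.07 after median centring and 0.54 under the control scaling, with 1 member at least 2-fold higher under the latter. Among nuclear receptors and coactivators, Ppara was higher and Ppargc1b (2.16-fold) lower, and the list stood at the 27.0th percentile (median -0.11, or 0.27 under the control scaling).

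**Figure D2:**
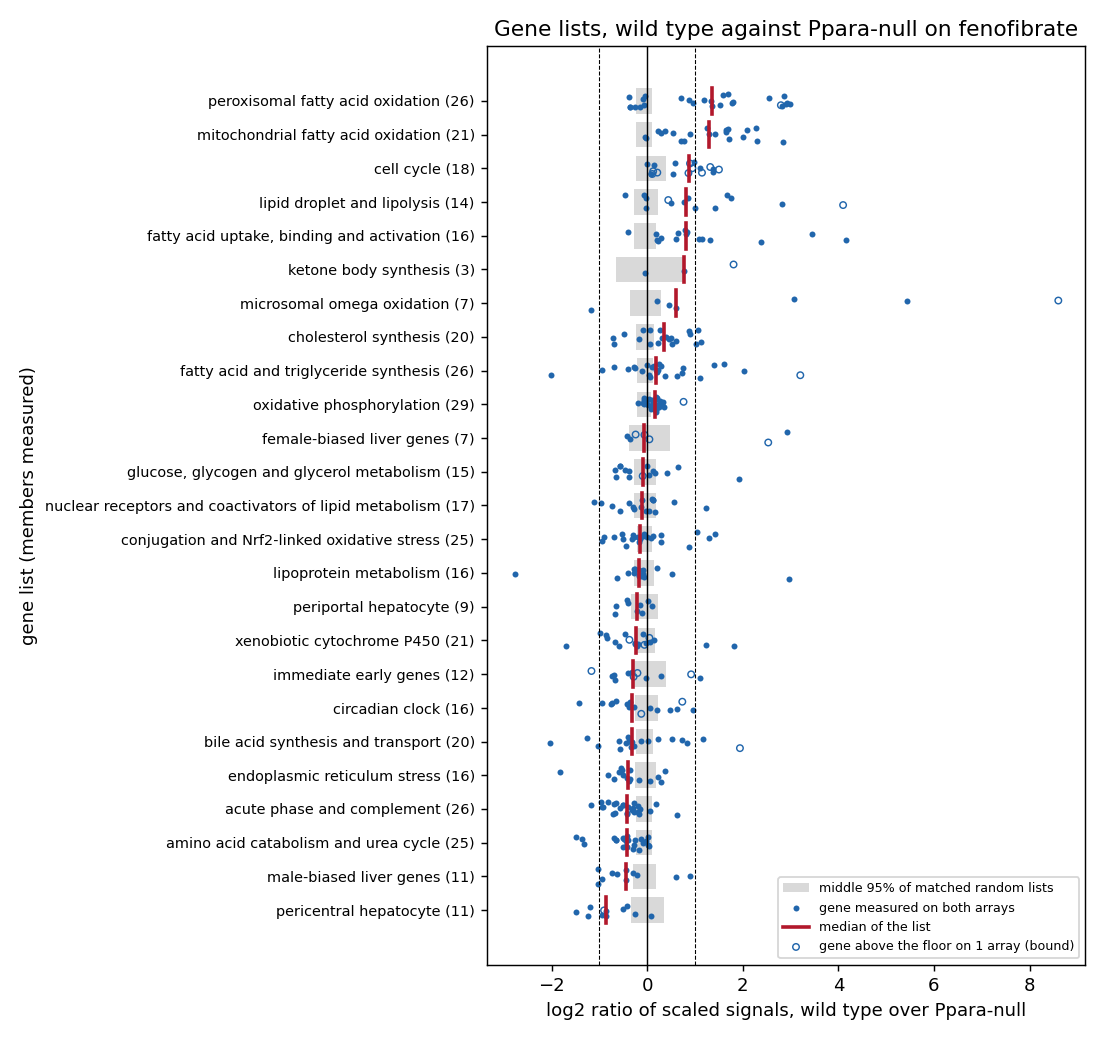
Log2 ratios of wild type over Ppara-null (x axis) for the measured members of 25 gene lists (y axis, number of members in brackets). Points are genes, open points bounds, red bars list medians and grey bands the middle 95% of 10000 matched random lists; the peroxisomal (2.55-fold) and mitochondrial (2.44-fold) lists lie farthest to the right and the pericentral list (-0.87) farthest to the left.

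Of the 25 lists, 10 lay above and 8 below the middle 95% of their matched lists, where 0.625 would be expected in each tail for independent genes. Members of a list are not independent and some lists share genes, so the excess over 0.625 does not measure chance. Of the 18 lists outside, 14 stayed outside on the same side of their matched lists in all 8 alternatives for which a percentile was computed. The exceptions were ketone body synthesis, immediate early genes, fatty acid and triglyceride synthesis and the circadian clock. Median centring and both control scalings shift all log2 ratios alike, so by construction they cannot move a list against its matched lists. Only the other alternatives bear on this count. Kupffer cell and macrophage markers were lower in wild type, with a median log2 ratio of -0.44 (67 of 10000 as low), or -0.06 under the control scaling, and Cd5l 2.12-fold lower. Endothelial markers (-0.24), stellate cell and fibroblast markers (-0.07), cholangiocyte markers (-0.24), T and NK cell markers (-0.42), neutrophil markers (0.38), pancreas markers (-0.32) and skeletal muscle markers (0.45) had medians inside the matched lists. Single members stood apart: of 5 muscle markers, Acta1 (at least 4.54-fold, 1223.5 against 229.7) and Tnnt3 (at least 2.04-fold) were higher. Endothelial Pecam1 was at least 2.36-fold higher and pancreatic Cela1 2.03-fold lower. The null signals of Acta1, Tnnt3 (549 against 11.6) and Pecam1 (636.9 against 228) lay under the brightest Bacillus control on the null array (422.4). They cannot be told from background, and the 3 bounds hold against the main floor only and are smaller with the floor at that control. Under the control scaling the endothelial, stellate, cholangiocyte and pancreas medians turned positive, at 0.14, 0.31, 0.14 and 0.06, and the median of T and NK cell markers was 0.22 with the floor at the 25th percentile. The 3 measured erythroid markers had a median of -0.72 (percentile 1.11). Only Alas2 of these was above the floor on both arrays, since Slc4a1 was under it in wild type (193) and Hba-a1 in null (250.8). B cell and adipocyte markers had 2 and 1 measured members, too few for a percentile, with medians of -0.73 and 1.09. The adipocyte member was Fabp4, also in the uptake list, and Adipoq was under the floor on both arrays, so that median says little of adipocytes. The ratio of 3' to 5' probe sets was 1.89 in wild type and 2.27 in null for b-actin, and 0.68 and 0.74 for Gapdh. For pyruvate carboxylase it was 3.76 and 5.20, and for the transferrin receptor 3.20 and 1.39, so it differed between the arrays in opposite directions.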

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

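Of the tests in this part, the second probe set test was fixed before its result was seen, and the scaling test was settled after, because the way to scale to the controls was changed once a first result was known. Arrays carry probe sets for hybridization controls, transcripts from outside the mouse that are added before hybridisation. Scaling to them assumes that equal amounts went onto both arrays, which was not checked here. All 18 hybridization control probe sets were brighter on the null array, by a median of 1.30-fold (range 1.09 to 1.66), although both arrays had been scaled to the same mean. These probe sets lie outside the main measurement and there was no control sample to compare them with. Among the 3645 measured probe sets unnamed here, 181 were at least 2-fold higher in wild type and 78 at least 2-fold lower.

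The 365 genes called lower in wild type depended on the scaling. Scaled to the hybridization controls by the median of their log2 ratios, 29.9% of them stayed at 2-fold or more, and with the first way of computing this scaling 41.1% did. A common factor of this direction lowers the count by construction, so the scaling may account for many of the smaller calls if the controls are the truer scale. Noise of dim probe sets stays open as a partial cause: a second probe set measured on both arrays pointed the same way for 71.8% of 78 genes called lower (95% exact interval 60.5 to 81.4) and for 84.0% of 94 genes called higher, where 59.2% of 3744 genes under 2-fold had a second probe set of the same sign. Split after the result was seen, it was 79.0% of 62 lower genes whose main probe set reached 4 times the floor and 43.8% of the 16 dimmer ones (exact interval 19.8 to 70.1). Among higher genes it was 91.0% of 67 bright and 66.7% of 27 dim ones (46.0 to 83.5). These differences were not tested, and noise may account for part of the dim calls. Only genes whose main probe set was above the floor on both arrays entered this comparison. The 140 lower and 288 higher calls above the floor on 1 array only were left out, so it does not bear on them. Of the second probe sets of the 78 lower and 94 higher genes, 16.7% and 33.0% were themselves at least 2-fold apart. The difference between the directions was not tested, and whether the controls or the mean of all probe sets is the better scale was not settled by these data.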

How the results depend on the processing

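The scaling by the median of the control log2 ratios was chosen after seeing the data and the results of the scaling by the difference of the control medians. Floors at the brightest Bacillus controls were also chosen after, and the other alternatives before. No paired analysis was possible because each genotype has 1 array, and no replicate could be left out. The median log2 ratios of peroxisomal and mitochondrial fatty acid oxidation genes kept their direction and stayed above 1 under all 11 alternatives of scaling, floor and probe set, from 1.12 to 1.73 and from 1.19 to 1.66. Counts of genes moved with the floor, which by construction sets how many dim genes can pass: 2336 higher and 1650 lower with the floor at the 25th percentile, 157 and 98 at the 75th, and 3096 and 2177 with no floor. Floors at the brightest Bacillus controls gave 297 higher genes, all among the 651, and 303 lower. Those floors are higher on the null array than on the wild-type array, which by construction weighs against higher calls. Scaling to the hybridization controls gave 1350 higher and 150 lower genes by the difference of their medians, and 1759 and 109 by the median of their log2 ratios. The 1.5-fold threshold gave 1925 and 1438, and the 3-fold threshold 132 and 58. Other settings stayed within 1.5 times the main counts, at 507 to 621 higher and 268 to 507 lower genes. Of the 651 higher calls, 524 held with the median over the probe sets of a gene, and of the 365 lower calls 252. No named gene at 2-fold or more changed sign. Of the values of named genes under the alternatives, 1258 moved by less than the SD between probe sets (0.42) and 103 by more. Of list medians, 375 moved by less and 8 by more. Median centring and both control scalings shift all log2 ratios by a common amount under 0.42. Under these settings, gene values and list medians therefore count as moved by less by construction. Of 25 gene lists, 7 changed sign when scaled by the difference of the control medians and 10 when scaled by the median of the control log2 ratios. These sign changes follow by construction for lists whose negative median was smaller in size than the common shift. Of 18 lists outside their matched random lists, 14 stayed so in all 8 alternatives in which this was computed. Median centring and both control scalings cannot change this by construction. Low signals limit the dim genes: 1586 genes were above the floor in wild type only and 1395 in null only, so their ratios are bounds.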

Other observations

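The family scan and all tests in this part were chosen after the gene values were seen. Gene families were read from shared symbol stems, giving 314 families with at least 6 measured members. Of these, 8 lay above and 3 below the middle 99% of matched random lists, where 1.57 would be expected in each tail for independent genes. Members of a family are not independent, so the excess does not measure chance. Acyl-CoA thioesterases (Acot) had a median log2 ratio of 1.17 (1.08 to 1.69 under the alternatives), with 7 of 11 at least 2-fold higher in wild type, among them Acot7 (1.15) and Acot6 (1.17), which were in no list. The Abhd hydrolases had a median of 0.38, led by the monoacylglycerol lipase Abhd6 (2.97) and Abhd1 (1.58). Fabp (0.79), Elovl (0.62) and Aldh (0.30) families also had positive medians, as did Cox genes of cytochrome c oxidase (0.30, 16 of 21 positive), Mrpl genes of the mitochondrial ribosome (0.17, 32 of 47) and Psmd genes of the proteasome (0.25, 12 of 14). Each of these 6 families had members on both sides of 0. Under the alternatives the Abhd median ranged from 0.25 to 0.76, Fabp from 0.53 to 1.17, Elovl from 0.50 to 1.00 and Aldh from 0.07 to 0.68, and the Cox, Mrpl and Psmd medians from 0.17 to 0.68, 0.07 to 0.55 and 0.16 to 0.63.

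Cytosolic sulfotransferases (Sult) were the opposite case. All 8 measured members were lower in wild type, with a median log2 ratio of -0.93, from Sult5a1 (-1.55) and Sult1b1 (-1.04) to Sult2a8 (-0.31), and medians between -1.03 and -0.55 under the 11 alternatives. Lysine demethylases (Kdm) had a median of -0.55, with Kdm6a (-1.71), Kdm7a (-1.13) and Kdm6b (-1.12) lowest, but -0.17 under the control scaling and -0.27 with the median over probe sets. The Cyp family as a whole stood at -0.21 and turned to 0.17 under the control scaling. The metallothionein Mt1 was lower beside Mt2, at -1.19.

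Ppara signal that remained on the null array was not background-like and did not look like carried-over wild-type RNA. Cyp4a14 and Vnn1, among the brightest wild-type genes, kept at most 0.58% of their wild-type signal on the null array, against at least 36.0% for Ppara, which argues against admixture as the source. The lowest Ppara signal was 3.67 times the highest of the 27 Bacillus control probe sets on that array. A candidate explanation is a transcript of the targeted gene outside its disrupted part. With 0 of the 3 probe sets at the floor and the position of the disruption not known here, the data do not decide it, and binding of other transcripts to these probe sets was not tested.

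Scaling to the hybridization controls left the median of the lower pericentral genes at -0.49, so this scaling alone did not bring it to 0. That was more than 3 times the SD of the members over the root of their number (0.14). The members are not independent replicates, so this ratio is no test of scaling as the whole cause. With the median over probe sets the list stood at -0.51 (percentile 0.05), and this was not combined with control scaling. A common shift cannot move the list against its matched lists. A smaller share of pericentral cells in the wild-type pool may contribute. It predicts members that move alike, and their SD was 1.09 times the SD between probe sets of 1 gene, which neither bears it out nor excludes it, while Glul at 0.07 goes against it. A difference by genotype on the drug stays open and untested, with 1 pool per genotype.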
